A study of Chlamydomonas reinhardtii with 8 samples.

How the data were processed

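Total RNA from whole cells of the green alga Chlamydomonas reinhardtii, laboratory strain CC-124, was measured on 8 single-colour (Cy3) Agilent oligonucleotide arrays. Per the labels, 4 arrays held RNA of control cultures at 23 °C and 4 held RNA of cultures kept at 42 °C for 45 min. Groups and replicate numbers were taken from the sample titles. The design text of the series states 3 biological replicates while each group has 4 numbered arrays, and the labels do not say which arrays share a culture. Whether a given culture had been grown in the dark or in light before the treatment is not given per sample. The p-values measure the spread between these arrays, part of which may be technical. All 8 arrays lay on 1 slide. Controls and heat shock arrays alternated in its columns, and each of its rows held replicates of both groups.

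The scanner files hold an intensity per spot. Per the file headers, they were made with Agilent Feature Extraction 9.5.3.1 under protocol GE1-v5_95_Feb07, with spatial and multiplicative detrending of the signal and surrogate values for spots that could not be told from background. The deposited processed intensity is background-subtracted within each array and is not scaled between arrays. The files also give 0 or 1 flags for spots well above background, saturated, or non-uniform. A second table holds log2 values, with its making not given in the sources used here. Tested against the scanner signals, these deposited log2 values are centred on each probe's median (within 0.001 of 0 for 9999 of 10000 probes). After the same centring they followed the signals scaled to the 75th percentile with slopes of 0.99 to 1.00 and correlations of 0.991 to 0.998 across probes. The column medians of that table were -0.54, -0.48, -0.44 and -0.13 for control replicates 1 to 4 and -0.02, 0.64, 0.80 and 0.87 for heat shock replicates 1 to 4. Scale, centring and direction were thus found from this comparison, while the between-array scaling of that table was inferred from it and is not stated.

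The arrays hold 10000 probes of the alga in 15208 spots, 5208 of them spotted 2 times. Each probe has its own target name, and without annotation it is not known which probes share a gene. The files describe every probe as unknown, and the reference table (RefSeq, assembly Chlamydomonas_reinhardtii_v5.5, 17742 genes) pairs none of these names with a gene and lists no symbol other than locus tags. Values and counts are therefore given per probe. All 21 gene lists fixed before the data were examined (heat shock proteins, light harvesting, chlorophyll synthesis, ribosomal proteins and others) had 0 members that could be found, so no list test was run. The rule for named probes, fixed at the same time, takes per direction the largest fold changes among called probes whose groups do not overlap, and allows at most 2 probes per direction where only an ID is known. The 2 probes whose ID holds a word, 9999.PHOX and 10000.PilA1, were well above background on 0 arrays.

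For each array, spots flagged as non-uniform or population outliers were left out, which were 0.362% to 2.06% of the probe spots. The log2 processed intensities of a probe's spots were averaged, and the array's 75th percentile over probes was subtracted. A probe was tested if all its unflagged spots were well above background on at least 4 of the 8 arrays, counted without regard to group. It also had to have an unflagged spot on at least 1 array of each group. These 2 rules left 6921 probes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, 6 residual degrees of freedom), with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. Array-wide measures were compared with exact 2-sided permutation tests over all divisions of 8 arrays into 4 and 4, for which the smallest possible p is 0.0286, with Benjamini-Hochberg adjustment over the 11 measures. These tests treat the 8 arrays as separate samples, which the labels do not establish. Where a probe was dim on every array of a group, or saturated on every array of the brighter group, the fold is a lower bound. For the named probes a lower bound was also given where only some arrays of the dimmer group were dim. The bound sets the brighter group's mean against a mean over the dimmer group's arrays. Each of these arrays enters with the higher of the probe's own value and the array's lowest scaled signal among probes well above background. Of the 10 E1A spike-in probes, 5 were above background and unsaturated on every array, and their mean was used as a second reference for scaling. Plots were drawn with matplotlib 3.10.9.

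The test was checked on simulated data for this comparison, with the means and spreads of 6750 real probes and 200 changed probes. It recovered 8% of 2-fold, 60% of 4-fold, 92% of 8-fold and 94% of 16-fold changes, and 6.62% of its calls (9 probes) were false. When few probes change, a 2-fold change is thus rarely called with these arrays. In the real comparison far more were called, 72.6% of the tested probes, so the simulated shares do not carry over to it directly. The precision is limited by the number of arrays. Arrays with the same replicate number tended to deviate together from their group means. The correlations across probes were 0.11 to 0.27 for the 4 pairs against -0.22 to 0.16 for the 12 other pairs, with overlap. Arrays with the same number also lay side by side on the slide, so a shared slide position cannot be told apart from paired samples. The numbers were treated as pairing the samples in an alternative fit. The alternatives changed the scaling (median, quantile, spike-ins), the background correction (normexp with an offset of 50), the filter on dim probes, the source of the values, the eBayes prior, a block for the replicate number or the slide row, and the arrays left out.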

Results

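The study measured how transcript levels in Chlamydomonas reinhardtii change when cells are moved from 23 °C to 42 °C for 45 min. Chlamydomonas is a unicellular green alga used as a model of photosynthesis and of the heat shock response. The arrays carry 10000 oligonucleotide probes and 10 spike-in probes, and each of the 2 groups had 4 arrays. The probes are known only by ID here, so the text gives array-wide measures, counts of probes and the 2 probes per direction with the largest fitted changes. A level is a log2 signal minus the array's 75th percentile unless stated otherwise.

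The heat shock arrays were dimmer across most of the transcriptome, while the spike-in controls were not. The median probe signal was 765, 694, 650 and 569 on control replicates 1 to 4 and 138, 78.0, 82.6 and 83.3 on heat shock replicates 1 to 4. On the log2 scale this was 9.38 ± 0.18 (SD, n = 4) in controls and 6.53 ± 0.38 (SD, n = 4) after heat shock, a 7.18-fold lower median (exact permutation p = 0.0286, adjusted p = 0.0449, the smallest the design allows before adjustment). The spike-in mean was 12.52 ± 0.28 in controls and 13.04 ± 0.41 after heat shock (SD, n = 4 each), a difference of 0.52 that did not pass the unpaired test (exact permutation p = 0.114, adjusted p = 0.126). Between arrays of the same replicate number the spike-in mean was higher after heat shock in 4 of 4 pairs, by 0.29 to 0.78, and a paired exact permutation test of 4 pairs cannot give a p below 0.125. Relative to the spike-ins, the median probe was 10.3-fold lower after heat shock (exact permutation p = 0.0286, adjusted p = 0.0449), and all 4 heat shock arrays lay below all 4 control arrays. The 99th percentile of signal was 1.63-fold lower relative to the spike-ins (exact permutation p = 0.0286, adjusted p = 0.0449), and the summed signal was 2.05-fold lower (exact permutation p = 0.0286, adjusted p = 0.0449). Both values include saturated probes, and on control replicate 1 and heat shock replicate 1, with 103 and 101 saturated probes, the 99th percentile itself lay at or near the scanner's limit, so these folds are not exact.

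**Figure D1:**
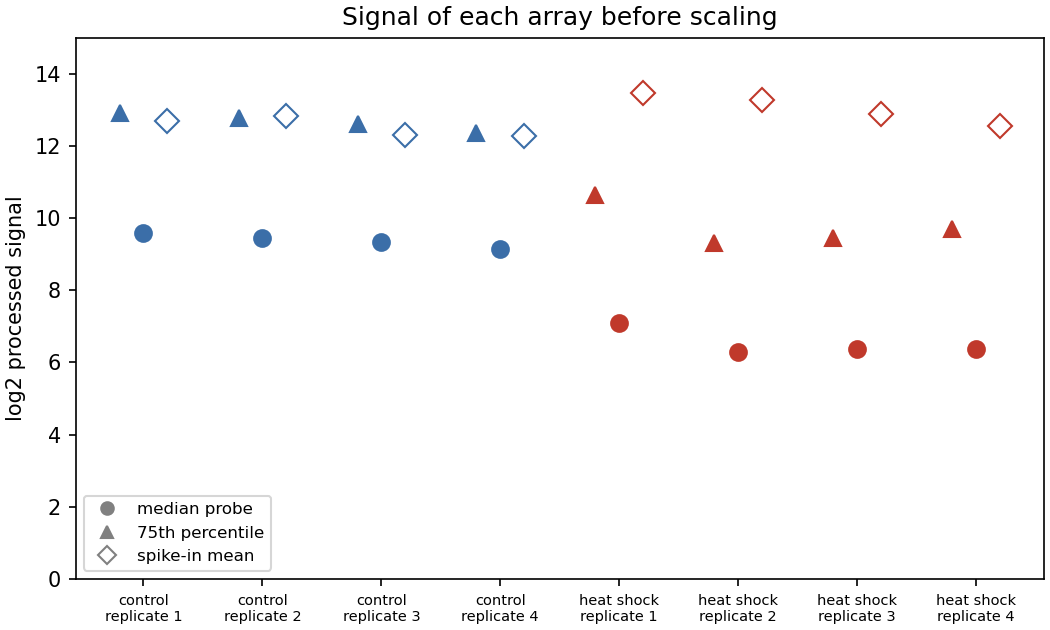
Log2 processed signal of each array before scaling, with the median probe (circles), the 75th percentile of probes (triangles) and the mean of 5 spike-in probes (open diamonds), controls in blue and heat shock in red. The medians lie between 9.15 and 9.58 in controls and between 6.29 and 7.10 after heat shock, while the spike-in means lie between 12.27 and 13.47 over all arrays.

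In the signals as read, the brightest probes held a larger share after heat shock. The 1000 brightest probes of an array held 83.7% ± 1.3 of the summed signal in controls and 95.02% ± 0.96 after heat shock (SD, n = 4 each; exact permutation p = 0.0286, adjusted p = 0.0449). The 100 brightest held 32.4% ± 3.0 in controls and 46.6% ± 8.0 after heat shock (SD, n = 4 each; exact permutation p = 0.0286, adjusted p = 0.0449). Here the groups nearly met, at 35.26% on control replicate 4 and 35.31% on heat shock replicate 1. For the 10 brightest, the shares of 4.21% ± 0.69 and 6.19% ± 1.55 (SD, n = 4 each) missed the threshold (exact permutation p = 0.0857, adjusted p = 0.105), with the share higher after heat shock in 4 of 4 pairs. Controls had 69.6% ± 3.7 of probes well above background against 58.7% ± 6.9 after heat shock (SD, n = 4 each), which also missed the threshold (exact permutation p = 0.0571, adjusted p = 0.0786) and was lower after heat shock in 4 of 4 pairs. Saturated probes numbered 26 to 103 on control arrays and 29 to 101 on heat shock arrays, so the shares of the brightest probes are lower bounds in both groups. The differences in these shares and their tests hold for the signals as read, and the true size of the differences is not known.

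Relative to the 75th percentile of each array, 2820 probes were higher and 2205 lower after heat shock among the 6921 tested, and 1896 were not called (limma, adjusted p under 0.05). Calls thus covered 72.6% of the tested probes. At least 2-fold changes were seen for 2726 higher and 2135 lower probes, at least 4-fold for 1982 and 1399, at least 16-fold for 621 and 239, and at least 64-fold for 187 and 3. All 4 heat shock arrays lay on one side of all 4 control arrays for 4657 tested probes, or 67.3%. For a single probe chance gives 2.86%. The probes share the same arrays and scaling, so a shift of whole arrays can part the groups for many probes together. The 1884 probes well above background on no array had a median log2 fold change of 2.26 under this scaling. The share of 67.3% is therefore a description and no test against chance. The interquartile range of the log2 fold change ran from -1.62 to 2.30, against a median SE of 0.39.

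The balance of higher and lower calls depended on the reference for scaling. Scaled to the spike-ins, 472 probes were higher and 5211 lower (limma, adjusted p under 0.05), and the median log2 fold change of the tested probes moved from 0.27 to -3.13. Quantile normalization gave 2227 higher and 2620 lower probes with a median of -0.22, and scaling to the array median gave 2748 and 2242 with a median of 0.24. Of the 2820 probes higher relative to the 75th percentile, 472 were also higher relative to the spike-ins, 1130 were lower and 1218 were not called. The change of reference moved the log2 fold changes of the probes almost alike, by a median of -3.40, so that lower calls stayed lower by construction. Quantile normalization turned 53 higher calls to lower.

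**Figure D2:**
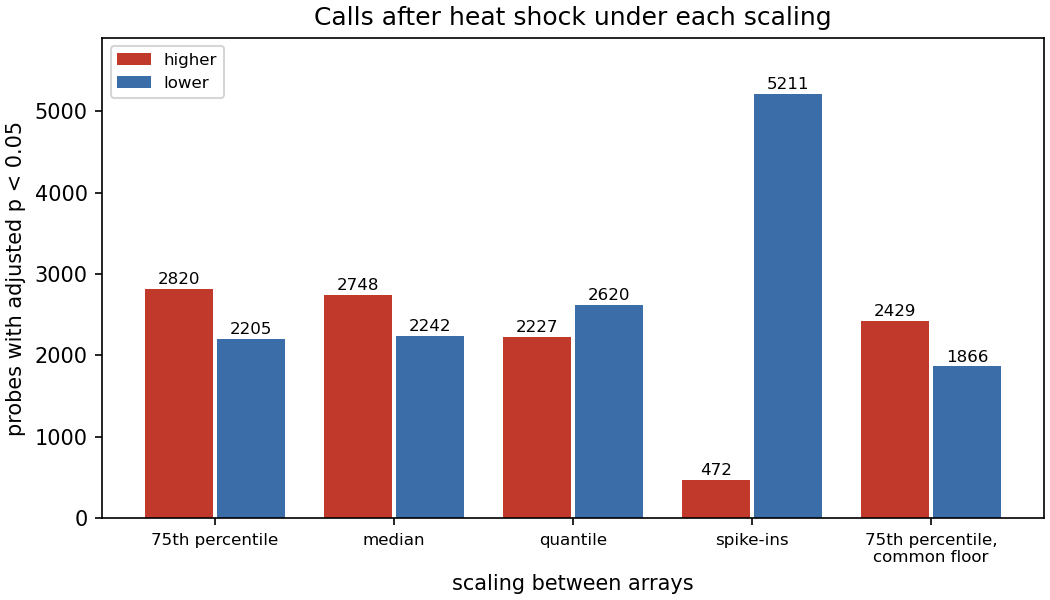
Number of probes with a limma adjusted p under 0.05 that were higher (red) or lower (blue) after heat shock, for 4 ways of scaling the 8 arrays to each other and for the 75th percentile with a common floor. Among these 5 settings, the higher calls range from 472 with spike-ins to 2820 with the 75th percentile, and the lower calls from 1866 with the common floor to 5211 with spike-ins.

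Under all of the 75th percentile, median, quantile and spike-in scalings, 472 probes (6.82% of those tested) were called higher after heat shock and 2123 (30.7%) lower. The 472 are the higher calls of the spike-in scaling, whose shift sets how large a rise must be to be among them. These 472 probes had a median change of 49.1-fold relative to the 75th percentile and of 4.66-fold relative to the spike-ins. In this set 75 probes were well above background on no control array, and with these controls at their detection limit the median was 41.4-fold. On the heat shock arrays, 469 of the 472 were well above background on all 4. The 2123 lower probes had a median change of 5.45-fold relative to the 75th percentile and of 57.4-fold relative to the spike-ins, and 377 of them were not well above background on any heat shock array. With those 377 at the detection limit of the heat shock arrays, the median was 4.77-fold relative to the 75th percentile.

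Detection differed between the groups for part of the probes. There were 77 probes well above background on all 4 heat shock arrays and on no control array, and all 77 were called higher (limma, adjusted p under 0.05). These probes were chosen by the same contrast between the groups, so their calls add no separate evidence of a rise. Their median change was at least 25.3-fold, 75 of them were at least 10-fold higher, 7 at least 100-fold, and the highest at least 9004-fold. These bounds rest on the control arrays' own detection limits under the 75th percentile scaling. With one common floor the median was 3.00-fold, with 8 probes at least 10-fold higher, the lowest 1.08-fold and the highest 1060-fold. Relative to the spike-ins the median bound was 2.40-fold. In the other direction, 466 probes were well above background on all 4 control arrays and on no heat shock array. Of these, 377 were called lower and 190 were at least 2-fold lower against the detection limit, the largest by at least 42.2-fold. With one common floor 119 were at least 2-fold lower, the largest by 31.8-fold. Relative to the 75th percentile, the detection limit lay between -6.19 and -3.88 on heat shock arrays and between -7.59 and -6.14 on control arrays. The 2 ranges overlap slightly. They hold on this scale only, since the 75th percentile itself differed (-2.88, log2, heat shock minus control). They do not show that a dim transcript was easier to detect on control arrays.

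Probes 32.A and 4877.C had the largest fitted rises, and their order was not measured, because control arrays below background and saturated heat shock arrays leave only lower bounds. Probe 32.A is a 54-base probe with the sequence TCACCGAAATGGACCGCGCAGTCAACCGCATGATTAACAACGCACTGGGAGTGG. Its level was -7.71 ± 2.50 in controls and 8.84 ± 0.53 after heat shock (SD, n = 4 each), a log2 fold change of 16.56 with an SE of 0.97 (limma adjusted p = 9.4e-08). Single arrays moved this value by over 1.5 times in fold, to a log2 fold change of 17.77 without control replicate 1 and of 15.89 without control replicate 2. It was well above background on 1 of the 4 control arrays, control replicate 1, where its signal was 457 against 8.29, 14.3 and 16.4 on the others. It was saturated on 1 heat shock array. With the 3 other control arrays at their detection limit, 32.A was at least 31685-fold higher after heat shock. Probe 4877.C, with the sequence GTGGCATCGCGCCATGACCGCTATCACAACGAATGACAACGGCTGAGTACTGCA, was saturated on all 4 heat shock arrays and well above background on 3 control arrays. With saturated spots at their value and the undetected control array at its detection limit, it was at least 53505-fold higher after heat shock, from a level of -6.67 ± 1.19 to 9.55 ± 0.62 (SD, n = 4 each; limma adjusted p = 3.5e-09). Both bounds, 14.95 and 15.71 on the log2 scale, were computed for the 75th percentile scaling with each array's own detection limit. Median scaling gave log2 fold changes above them, 16.52 for 32.A and 16.19 for 4877.C. Some other settings gave values below these bounds. The log2 fold changes of 32.A and 4877.C were 12.72 and 13.43 with one common floor, 14.14 and 14.69 with normexp correction, and 14.35 for both with quantile normalization.

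Probes 1409.C and 8637.D had the largest fitted falls, in an order that was not measured. Probe 1409.C is a 57-base probe with the sequence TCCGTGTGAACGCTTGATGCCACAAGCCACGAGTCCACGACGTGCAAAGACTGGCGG. Its level was 1.11 ± 0.48 in controls and -5.61 ± 0.79 after heat shock (SD, n = 4 each; limma adjusted p = 1.6e-07). No heat shock array showed it well above background, and it was at least 42.2-fold lower after heat shock. Probe 8637.D, with the sequence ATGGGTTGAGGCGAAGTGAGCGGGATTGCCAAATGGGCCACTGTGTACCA, was at 2.44 ± 0.29 in controls and -4.04 ± 1.13 after heat shock (SD, n = 4 each). Its log2 fold change was -6.48 with an SE of 0.50 (limma adjusted p = 6.3e-07), and it was well above background on 3 of the 4 heat shock arrays. With the other heat shock array at its detection limit, it was at least 73.6-fold lower after heat shock. These bounds too hold only for that scaling and detection limit, since the log2 fold changes of 1409.C and 8637.D were -4.14 and -5.32 with normexp correction and -4.99 and -5.92 with one common floor. The 4 probes kept their direction and their call under each of the 4 scalings, with log2 fold changes relative to the spike-ins of 13.16 for 32.A, 12.82 for 4877.C, -10.12 for 1409.C and -9.88 for 8637.D. Their place in the genome is not given here, because the sources used pair no probe with a locus.

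**Figure D3:**
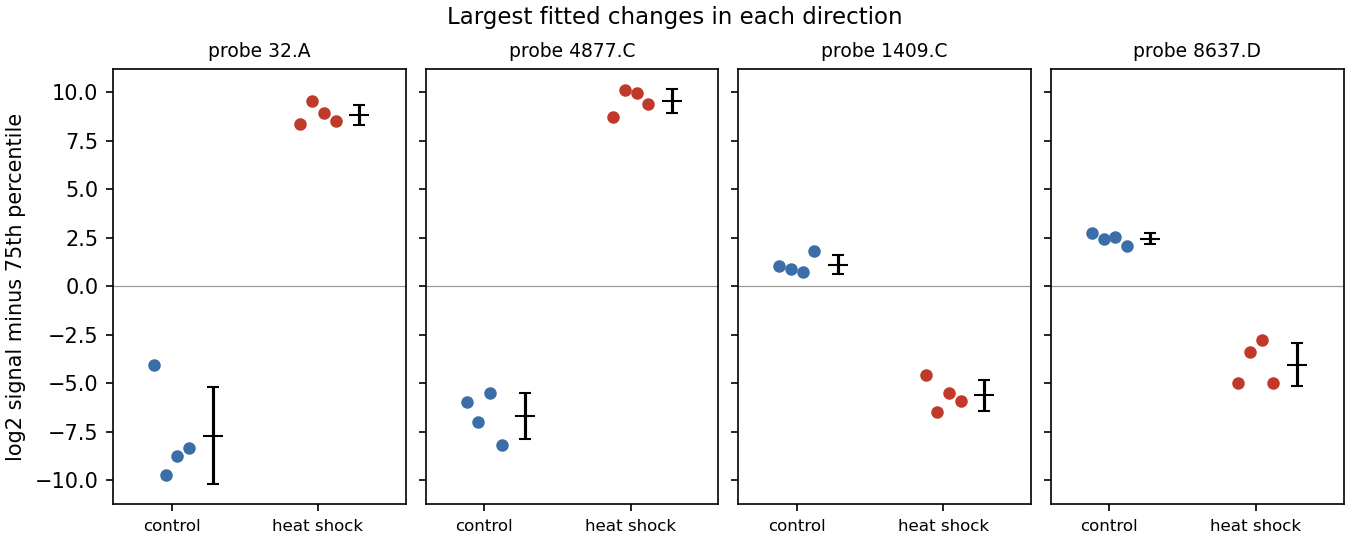
Level of the 4 probes with the largest fitted changes, 2 in each direction (log2 signal minus the array's 75th percentile) on the 4 control arrays (blue) and the 4 heat shock arrays (red), with the group mean and SD in black. For each probe the groups do not overlap, as in 32.A with means of -7.71 and 8.84.

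Among the 4488 probes well above background on all 8 arrays, the shares of higher and lower calls differed between levels of signal. This choice of probes removes dim transcripts that fell below the detection limit of the heat shock arrays, so the shares in the dimmest bin are partly set by it. The probes were divided by mean level into 5 bins of equal size, numbered 1 from the dimmest. In bin 1, 60.6% of probes were higher and 9.47% lower, with a median log2 fold change of 1.50. More probes were lower than higher in bin 2, with 28.1% higher and 40.5% lower, and in bin 3, with 29.0% higher and 39.2% lower. Bin 4 had 48.9% higher and 19.6% lower probes, and bin 5, the brightest, 75.3% higher and 5.68% lower with a median of 2.30. Relative to the spike-ins the median was below 0 in all 5 bins, at -1.90, -3.90, -3.83, -2.47 and -1.10 from bin 1 to bin 5. On that scale more probes were lower than higher in every bin, with 3.01% higher and 70.5% lower in bin 1 and 11.9% and 51.1% in bin 5. The brightest probes met the upper limit of the scanner. All 66 tested probes that were saturated on at least 1 array of each group were called higher relative to the 75th percentile, with a median log2 fold change of 2.88, close to the difference of 2.88 between the groups' 75th percentiles, and 0 of them were among the 472 called higher under all 4 scalings. No fold can be given for the 14 that were saturated on all 8 arrays.

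**Figure D4:**
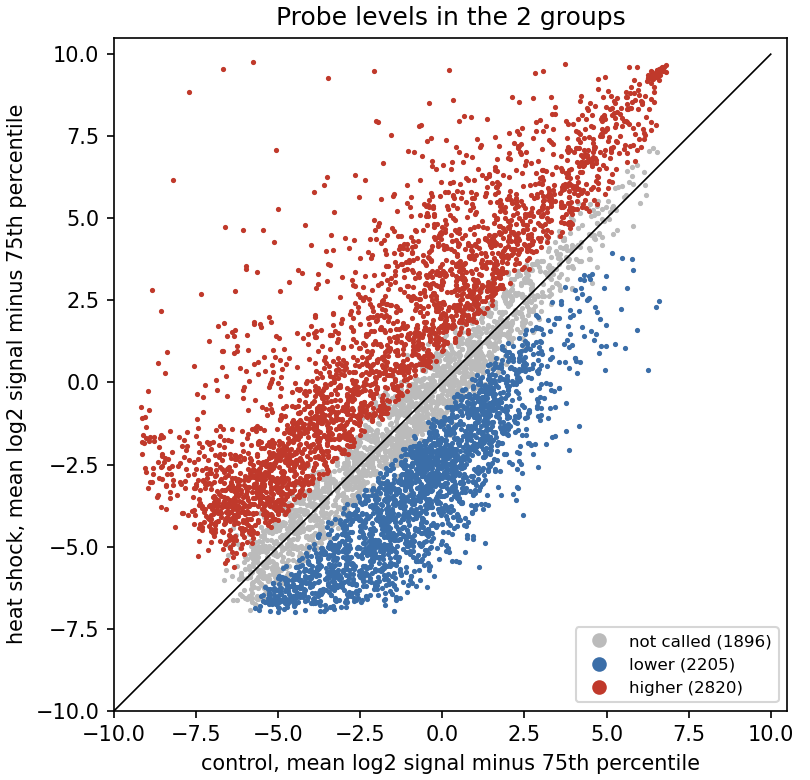
Mean level of the 6921 tested probes on the 4 control arrays (x axis) and on the 4 heat shock arrays (y axis), both as log2 signal minus the array's 75th percentile, with higher calls in red, lower in blue and uncalled probes in grey. The line marks equal levels, on which a probe has the same level in both groups; 2820 points are red and 2205 are blue.

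Across the same 4488 probes, which are not independent replicates, the mean levels of the 2 groups correlated at 0.66 (Pearson) and 0.62 (Spearman). Arrays of one group correlated at 0.91 to 0.99 in pairs, and arrays of different groups at 0.59 to 0.67.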

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

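Heat shock replicate 1 stood apart in brightness: its median log2 signal was 7.10 against 6.29, 6.37 and 6.38 on the other heat shock arrays, a gap of 0.885 of the group's range. Of the 30 sets of 4 arrays examined in this way, covering 11 array-wide measures and the 4 named probes in each group, 1 stood apart, where chance gives about 1.5. Without this array, 2817 probes were higher and 2221 lower. The tests of the dimmer heat shock signal, the test on probes that were well above background on no array, the tests of the GC trend, and the common floor and GC trend alternatives were chosen after the results were seen.

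The heat shock arrays were 10.3-fold dimmer relative to the spike-ins at the median probe. Scanning or hybridization that dimmed whole arrays would have lowered the spike-ins as well, and these were 0.52 higher on the log2 scale, more than the 0.41 SD between heat shock arrays. One common loss of labelled RNA cannot be the only change either, since 68.3% of the 4488 probes measured on all arrays differed by over 2-fold from the median shift (limma, adjusted p under 0.05). A lower yield or quality of the heat shock RNA, added to changes of single transcripts, cannot be told apart from a true fall of most messages, because it would follow the groups, whose arrays were 2.78 apart at their nearest (log2, median minus spike-in). A true fall of most transcripts after heat shock stays open as the biological explanation and was not tested.

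Of the 2820 higher calls, 345 were not well above background on all heat shock arrays. Scaling to the 75th percentile raises the background of dim arrays: the 1884 probes that were well above background on no array, and so carry no measured signal, had a median log2 fold change of 2.26 (quartiles 2.07 and 2.43). This is consistent with a background limit raised by the scaling as a source of the dim higher calls. With one floor common to all arrays, 65 of the 345, or 18.8%, were still called higher and none was lower, so a rise of some of these transcripts stays open.

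Under the scaling of the reported fit, probes rich in G and C tended to be higher after heat shock. The median log2 fold change of tested probes was -0.07 at 50 to 55% GC, 1.10 at 60 to 65% and 2.32 above 65%. Scaling to the spike-ins moved the log2 fold changes by -3.90 to -2.95, so these medians are all negative on that scale. The rise of GC-rich probes thus holds relative to other probes and not relative to the spike-ins. The trend was weak, with a Pearson correlation of 0.12 between GC and log2 fold change over all tested probes. The bin above 65% held 195 probes. With one common floor the slope over all tested probes was 0.49 ± 0.07 (SE, log2 per 10 percentage points of GC), against 0.79 ± 0.08 without it, so how far a raised background limit explains the trend stays open. A GC bias between arrays regardless of group is argued against by the slopes of array pairs with the common floor, which were at least 0.30 in all 16 pairs across groups and at most 0.24 in the 12 pairs within a group. With the control level in the model the slope was 0.25 ± 0.07, and a link to the low control levels of GC-rich probes stays open as well.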

How the results depend on the processing

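The values with replicates 2 and 3 averaged, a common floor, the GC trend removed, saturated probes left out, detection required in the brighter group, single slide rows, and the paired test of array-wide measures were chosen after seeing the data. Scaled to the spike-ins, 472 probes were higher and 5211 lower, 454 and 5138 of them at least 2-fold, and the median log2 fold change of the tested probes reversed to -3.13 from 0.27; under quantile normalization it reversed to -0.22. The 75th percentile and the spike-ins part as references because the first differed by -2.88 (log2, heat shock minus control) and the spike-in mean by 0.52. The origin of the lower probe signal stays open. With no filter on dim probes, 5273 were higher, 5203 of them at least 2-fold, because 9973 probes were then tested, many at background. Requiring detection on all 8 arrays left 4488 probes, with 1038 lower, 983 of them at least 2-fold, since probes that fell below background are removed. In slide row 1 alone (2 arrays against 2), 1876 were higher and 1319 lower, all 1319 at least 2-fold, and in row 2 alone 2485 and 1907. Normexp correction gave 3332 higher and 1664 lower, or 66.7% higher among calls against 56.1% in the reported fit, 45.9% under quantile normalization, 70.8% without the filter and 67.8% with detection on all arrays; 55 probes went from lower to higher under normexp. With the replicate number as a block, 2895 were higher and 2305 lower, 2796 and 2188 of them called the same way without it, so the pairing moved no count by over 1.5 times; with the slide row as a block there were 2767 and 2167. With arrays paired by replicate number, the exact permutation p of each array-wide difference that had passed was 0.125, the smallest that 4 pairs can give, so this test cannot pass the threshold; all 4 pairs went the same way for the median signal (-2.84, log2), the 75th percentile (-2.88), the median, 99th percentile and summed signal minus spike-ins (-3.36, -0.71 and -1.04) and the shares of the 100 and 1000 brightest probes (14.2 and 11.3 percentage points). The authors' value table gave 2752 and 2276 of 6923 tested, replicates 2 and 3 averaged 2658 and 2084, the common floor 2429 and 1866, and leaving out each array in turn 2685 to 2817 and 2074 to 2229. The calls of the 4 named probes kept their direction and threshold wherever they were tested. Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, gave as many calls for each of the 4 counts. These were 2820 higher, 2205 lower, and 2726 and 2135 at least 2-fold. The highest of the others was 0, the slide row split included. A share of 1 in 35 is under 0.05 but is the smallest that these splits allow, and it does not exclude chance. The 8 splits that part all 4 pairs (5025 real calls, highest other 0) are too few for a share under 0.05. The other splits mix the groups, which widens their spread, so their 0 is no measure of false calls. Dim signal and saturation limit the folds of the dimmest and brightest probes. The list tests (camera, fry) were not run because no list had a member, and the rule for several probes per gene was not applied, because each target name has 1 probe.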

Other observations

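The 4 arrays of each group were not equally similar. The SD of the log2 difference between 2 arrays, over the 4488 probes measured on all arrays, was 0.38 for control replicates 2 and 3. It was 0.70 for control replicates 1 and 4 and 0.80 to 1.02 for the remaining pairs of controls. For heat shock arrays it was 0.54 for replicates 2 and 3, 0.78 for replicates 1 and 4, and 0.89 to 1.37 for the remaining pairs. Spots of one probe within an array differed by an SD of 0.13 to 0.25. This is noise within an array and does not show whether replicates 2 and 3 came from separate cultures. They were counted as separate samples because the labels number them so.

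Some probes read opposite strands of a shared sequence. Among the 9 tested pairs of probes in which one shares 25 bases in a row with the reverse complement of the other, the median absolute difference in log2 fold change was 2.33, against 2.61 for random pairs of tested probes, a difference that was not tested. The 1 pair that shares 25 bases on the same strand differed by 0.10.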
